A study of Mus musculus with 11 samples.

How the data were processed

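Total RNA from laser-captured sympathetic ganglia of 78-week-old male mice was measured on 11 Affymetrix arrays, 6 from Apoe-deficient and 5 from wild-type animals, per the labels. The deposited values are linear probe set signals, that is, intensity values, and the authors used GCOS 1.4 to make them, per the submitters' processing notes. The signal algorithm, the detection calls and any later step by the authors are not given in the sources used here. Each deposited array had a 2% trimmed mean signal near 500.2 while its quantiles differed from those of the other arrays, so the arrays had been scaled to a common mean and not quantile normalised. No detection call was used, and the median signal per array ran from 163 to 188.6. The number of arrays limits the precision of every comparison.

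The table held 22690 probe sets, of which 64 were array controls and were left out of the tests. Of the remaining 22626 probe sets, 20380 carried 1 gene symbol in the platform annotation used, 691 carried several and 1555 carried none. The gene identifiers of 20351 single-gene probe sets were found in the RefSeq table of the assembly GRCm38.p6, and 0 symbols needed updating. That table served only for names and for the order of genes along a chromosome, because the genome build behind the annotation is not given in the sources used here. Some genes of the lists below had no single-gene probe set in the annotation used, and they were not analysed here: 913 of the 1061 distinct names were covered.

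Signals were taken to log2(signal + 16) and quantile normalised across the 11 arrays. A probe set was kept where its value exceeded the 40th percentile of all values in at least 5 arrays, and each gene was represented by its single-gene probe set of highest mean. Differences are therefore on the log2(signal + 16) scale, which understates the change of low genes. Genes were tested with limma 3.58.1 in R 4.3.3 (moderated linear model with an intensity trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05, and every adjusted p of a gene comes from this model. Apoe was also tested by an exact two-sided permutation test. Figures were drawn with matplotlib 3.10.9.

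Before the data were examined, 41 gene lists of cell types, pathways and ribosomal proteins were fixed, and the 34 with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01. Two-sided p-values were adjusted over those 34 lists. A list score was the mean over members of the log2 value minus the gene's mean over all arrays. Exact two-sided permutation tests of the list scores, adjusted over the same 34 lists, were added after the camera results and the counts from regrouped arrays had been seen.

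The genes named were fixed by rule before the data were examined: Apoe, the 10 largest changes in each direction among genes past the threshold, the 3 members of smallest p in each called list in the direction of its shift, and the 2 members of smallest p in the noradrenergic neuron, satellite glia, macrophage and cholesterol lists. Unnamed predicted genes were skipped. Other genes named as examples of a list were chosen after their values were seen: Ctss, Mpeg1, Cd68, Mrc1, Csf1r, Cd163, Adgre1, Cd14, C1s1, C1qb, C1ra, Serping1, Cfb, H2-Ab1, Ccl9, Cxcl12, Pou2af1, Ngp, Ltf, Ctsh, Ctsc, Scn3b, Kcnab2, Avil and the called neighbours of Apoe.

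Alternatives covered the step between arrays, the pseudocount, the filter, the probe set rule, the variance model, array weights, each array left out, a replicate block and other list tests. In a simulation on the real gene means and spreads over 8433 genes with independent errors, the gene test recovered 24% of genes changed by 0.5 log2 units, 80% of those changed by 1, 98% of those changed by 2 and 100% of those changed by 3, and made 6 false calls. The list test called 0 of 34 unshifted lists in data simulated with independent genes. Real genes are correlated, and regrouped real arrays gave called lists.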

Results

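Sympathetic ganglia, the clusters of noradrenergic nerve cells and glia outside the spinal cord, were profiled in aged male mice that lack apolipoprotein E and in wild-type mice. Apolipoprotein E is a lipid carrier, and mice without it develop atherosclerosis. The series title places the comparison in the exchange between the diseased aorta and the peripheral nervous system. The 78-week-old mice gave 6 Apoe-deficient and 5 wild-type arrays. The tissue was isolated by laser capture, and the labels do not tie each array to an animal. If arrays share an animal, the p-values below are too small. Otherwise they set the group difference against the spread between these samples, which may in part be technical. Rank correlations between arrays ran from 0.93 to 0.98 within the Apoe-deficient group, from 0.95 to 0.97 within the wild-type group and from 0.91 to 0.97 between groups, and 0 arrays held identical values.

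Apoe was the most strongly lowered named gene and checked the labels. Its deposited signal was 143 ± 84.6 (SD, n = 6) in Apoe-deficient ganglia and 15155 ± 3020 (SD, n = 5) in wild-type ganglia. The highest Apoe-deficient array had 268.2 and the lowest wild-type array 11830.3, so each of the 11 arrays lay on the side its label gives. The log2 difference was -6.75 (SE 0.44, limma adjusted p = 1.88e-06), and the exact two-sided permutation p was 0.0022, the smallest that 462 splits can give. One Apoe-deficient array, replicate 3, had a signal of 7.2, below the others of its group.

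The 10 largest increases included antibody and mast cell genes. The antibody genes Jchain (log2 difference 4.33, SE 0.69) and Ighm (3.76, SE 0.68), which plasma cells transcribe, were among the largest increases. They were joined by the mast cell protease genes Mcpt4 (2.47, SE 0.52) and Tpsb2 (2.03, SE 0.36). Igkv8-30, Iglv1, Igkv9-120 and Igk, also antibody genes, rose by 4.58, 3.84, 3.03 and 2.39. In wild-type replicate 4, Ighm (log2 value 13.8) and Igkv8-30 (13.4) lay near the Apoe-deficient means (14.0 and 13.4). Leaving out 1 array at a time gave 3.96 to 5.05 for Jchain, 3.37 to 4.67 for Ighm and 4.02 to 5.71 for Igkv8-30. Calb2, which encodes the calcium-binding protein calretinin, rose by 3.12 (SE 0.38) and lay above all wild-type arrays in 6 of 6 Apoe-deficient arrays. Slc35f4 rose by 2.42 from a low wild-type signal of 8.66 ± 5.60 (SD, n = 5), so the size of its change is uncertain. Over the alternative settings it ran from 1.38 to 3.63, and the Calb2 difference from 2.22 to 3.69. Probe sets of antibody genes read closely related sequences, so these genes cannot be taken as separate measurements. Probe sets of 1 gene disagreed in size: the others past the filter gave 7.08 for Igk, 0.83 for Igkv9-120 and 0.58 to 4.36 for Ighm.

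The largest decreases after Apoe were smaller. Erdr1 was lower (log2 difference -2.04, SE 0.26), as were Cnmd (-1.59), the amino acid transporter gene Slc1a5 (-1.40) and Nudt19 (-1.35, SE 0.11, adjusted p = 2.00e-05). The transcription factor genes Myrf (-1.28) and Isl2 (-1.09) were lower too, with the trypsinogen gene Prss2 (-1.18), the proteoglycan gene Bcan (-1.04) and the Wnt antagonist gene Dkk2 (-1.02). All 9 passed the threshold. Another probe set of Nudt19 gave only -0.35, and the mean of its probe sets -0.85. Nudt19 and Slc1a5 lie on chromosome 7, which also holds Apoe.

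In all, limma called 163 of 8433 genes, 106 higher and 57 lower in Apoe-deficient ganglia. The balance of directions moved with the setting: 290 were higher and 378 lower with array weights, and 135 higher and 132 lower without wild-type replicate 4. The 2 groups did not overlap for 115 of the called genes. Over all tested genes that share was 2.96%, where chance gives 0.433%. The count moved with single arrays: it was 260, 106, 75 and 100 without Apoe-deficient replicates 1, 2, 3 and 4, and 80, 77, 96, 267 and 77 without wild-type replicates 1, 2, 3, 4 and 5. Of the 38 called genes named by rule besides Apoe, 23 kept their call in each fit without 1 array that measured them, or 24 if each gene's probe set was held, a check added after the result was seen. The other 14, among them Igkv8-30, Mcpt4, Slc35f4, Cnmd, Myrf, Prss2 and Dkk2, lost it in at least 1. Without Apoe-deficient replicate 3, Igkv9-120 was represented by its other probe set (0.92, adjusted p = 0.32), while the same probe set gave 2.97 (adjusted p = 0.0132).

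**Figure D1:**
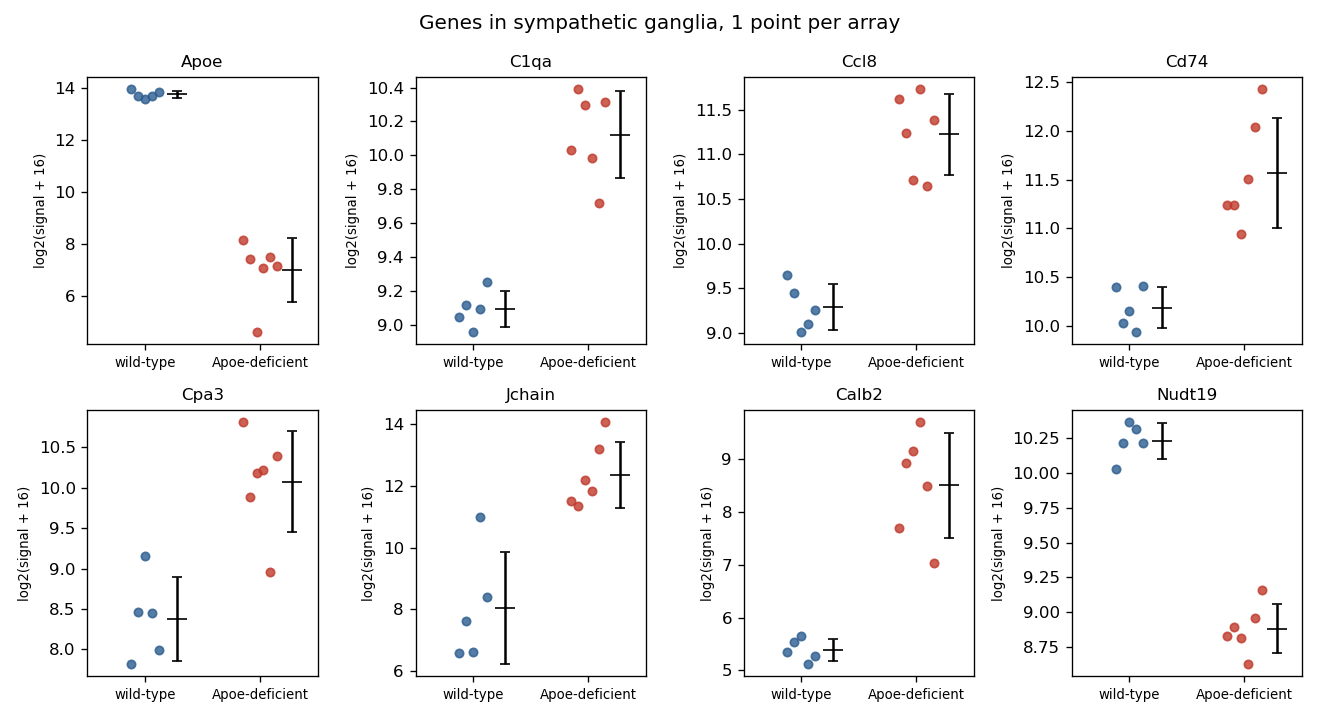
Log2(signal + 16) after quantile normalisation of 8 genes in wild-type (blue, n = 5) and Apoe-deficient (red, n = 6) ganglia, 1 point per array, with the mean and SD in black and a separate vertical axis per gene that does not start at 0. Apoe and Nudt19 were lower in every Apoe-deficient array than in any wild-type array, and C1qa, Ccl8, Cd74, Jchain and Calb2 were higher, while 1 Apoe-deficient array overlapped the wild-type range for Cpa3.

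The arrays also differed in technical measures. The signal of the hybridisation controls fell into 3 levels: Apoe-deficient replicates 2, 3 and 4 were low, Apoe-deficient replicate 5 and wild-type replicates 3, 4 and 5 in the middle, and Apoe-deficient replicates 1 and 6 and wild-type replicates 1 and 2 high. The group means of that signal did not differ past the threshold (exact permutation p = 0.35). Poly-A control signals were 184.5, 566.2 and 441.8 in the 3 low arrays and at least 1233 in the others. On the first principal component of the gene values (32.3% of the variance) the 3 low arrays lay at -19.5, -25.9 and -21.2. The other Apoe-deficient arrays lay from -4.83 to -2.50 and the wild-type arrays from 0.24 to 23.8. With the hybridisation control level as a block, an alternative chosen after seeing the data, limma called 45 genes, 36 of them among the 163. Within the high level, 2 arrays against 2 gave 4 calls, with median differences of 0.68 for macrophage, 0.71 for MHC class II and 0.99 for complement genes and 5.69 for Jchain. The middle level held 1 Apoe-deficient array, too few to separate the genotype from that sample; its macrophage median was 0.39, its MHC class II median 1.04, its complement median 0.10 and its Jchain difference 4.53, and the low level held 1 group only. Without the 3 low arrays 24 genes were called, 21 of them among the 163. The Apoe difference was -6.16 within the high level and -6.17 with the block.

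Gene lists were tested next, and the count of called lists needs its reference value beside it. The preset-correlation test called 15 of 34 lists, 11 higher and 4 lower. When the 11 arrays were regrouped at random, the same test called a median of 9 lists, and 14 of 100 splits, the real one included, called 15 or more. The number of called lists therefore did not exceed what regrouped arrays gave. With an estimated correlation 0 lists were called by camera, 6 had an unadjusted p under 0.05 and fry called 10. Exact permutation tests of the list scores, which use the arrays as the unit, gave an adjusted p under 0.05 for 8 lists. These were macrophage, complement, MHC class II, B and plasma cell, chemokine and cytokine, neutrophil and mast cell, fibroblast and extracellular matrix, and axon guidance. A test that regrouped only within control levels was added after the result was seen, and its smallest possible p, from 24 regroupings, is 0.042. Its unadjusted exact permutation p was 0.042 for macrophage, MHC class II, B and plasma cell, and chemokine and cytokine genes. It did not pass for the other 4. The NF-kB and lysosome lists, which are not among the 8, also reached 0.042, so this test did not single out the immune lists. These p-values were not adjusted over the 34 lists.

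Macrophage genes were higher as a group. Of 24 measured members 9 rose and 0 fell over all genes tested, and 18 rose when adjusted over the list alone. The median log2 difference was 0.68. The chemokine gene Ccl8 (1.93, SE 0.20), the lysozyme genes Lyz1 (1.46) and Lyz2 (1.19) and the protease gene Ctss (1.20) rose, and so did Mpeg1, Cd68, Mrc1, Tyrobp and Csf1r. Csf1r stood close to the threshold (adjusted p = 0.0498). Adgre1 (0.07) and Cd14 (0.02), also macrophage genes, did not pass. Lyz1 and Lyz2 are near-identical in sequence, so they cannot be taken as separate measurements. Of the other Lyz1 probe sets, that past the filter gave 1.78 and that below it -0.13. The list's exact permutation p was 0.0022 (adjusted 0.021), and camera gave an adjusted p of 0.083 with an estimated correlation. The number of called members was 16 with array weights, 5 without Apoe-deficient replicate 3, 3 with the control level as a block and 2 without the 3 low arrays, where the mean shift was 0.59 and 0.61 against 0.70 with all arrays and no block.

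Complement genes followed. Of 14 measured members 7 rose and 0 fell, and 10 rose when adjusted over the list alone. The chains of C1q, the recognition protein of the classical pathway, rose by 1.43 (C1qc, SE 0.15), 1.03 (C1qa, SE 0.13) and 0.58 (C1qb, SE 0.13). C1s1, C1ra, Serping1 and Cfp rose as well, Cfp losing its call without wild-type replicate 5 (log2 difference 1.64, adjusted p = 0.0504), and Cfb (1.19, adjusted p = 0.053) did not pass. The 7 calls became 2 without wild-type replicate 5, 3 without wild-type replicate 1 or Apoe-deficient replicate 4, 4 without Apoe-deficient replicate 2 or 3 or wild-type replicate 2, and 3 with the control level as a block (mean shift 0.71, SE 0.18, against 0.72, SE 0.13) or without the 3 low arrays (0.58), and 4 with the replicate number as a block. Within control levels the exact permutation p was 0.083. The exact permutation p of the score was 0.0043 (adjusted 0.021), and camera gave an adjusted p of 0.13 with an estimated correlation.

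Genes of antigen presentation by MHC class II rose in 5 of 9 measured members, and in 6 when adjusted over the list alone. Cd74, the invariant chain gene, rose by 1.38 (SE 0.22), H2-Eb1 by 1.03, H2-Aa by 0.82 and H2-Ab1 by 0.71. Ctss, named above among the macrophage genes that rose, is on this list too. Ccl8 is on both the macrophage and the chemokine lists, so these lists share called members. The exact permutation p was 0.0022 (adjusted 0.021), and the camera adjusted p with an estimated correlation was 0.13. Without the 3 low arrays 3 members were called and the mean shift was 0.76 against 0.64.

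Further immune lists held changed members. In the B and plasma cell list Iglv1, Jchain and Ighm rose, 3 of 9 members, and 4 when adjusted over the list alone. Pou2af1 (1.94, adjusted p = 0.075) did not pass, nor did the remaining members, which differed by -0.19 to 0.56. The median of the list was 0.56, so its mean shift of 1.67 rested largely on the antibody genes. The exact permutation p was 0.0022 (adjusted 0.021) and the camera adjusted p with an estimated correlation 0.24. Without the 3 low arrays 0 members were called, although the mean shift was 1.85 against 1.67, and with the control level as a block it was 2.15 (SE 0.43). In the neutrophil and mast cell list, Cpa3, Tpsb2, Cma1 and Mcpt4 rose, 4 of 9 members, and these are mast cell protease genes. The neutrophil genes Ngp (-0.53) and Ltf (-0.38) did not pass. When adjusted over the list alone 5 rose and 1 fell, the exact permutation p was 0.0043 (adjusted 0.021), and the camera adjusted p with an estimated correlation was 0.28. The 4 calls became 1 without Apoe-deficient replicate 3, 2 without Apoe-deficient replicate 4 or wild-type replicate 5, and 0 with the control level as a block (mean shift 0.84, SE 0.29, against 0.83, SE 0.20) or without the 3 low arrays (0.66). With the replicate number as a block 2 were called, and within control levels the exact permutation p was 0.083. Without the filter on low values 4 members were still called. The mean shift of the list was then 0.36 and its camera adjusted p at the preset correlation 0.21, against 0.0072 with the filter. Another probe set of Tpsb2, below the filter, gave 0.08. Among 26 chemokine and cytokine genes 5 rose, namely Ccl8, Ccl6 (1.86), Ccl9 (1.22), Cxcl12 (1.25) and Il33 (0.91). Adjusted over the list alone 8 rose and 1 fell, with an exact permutation p of 0.0043 (adjusted 0.021) and a camera adjusted p of 0.13 with an estimated correlation. The 5 calls became 8 with array weights, 3 without Apoe-deficient replicate 3 or wild-type replicate 1, 2 or 5, and 1 with the control level as a block (mean shift 0.36 against 0.41) or without the 3 low arrays (0.43). Another probe set of Ccl6 gave 1.11. T and natural killer cell genes were too few to test, with 4 measured and 0 called.

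Matrix genes shifted through small differences. Of 22 fibroblast and matrix genes only Postn passed (1.10, SE 0.18), and 5 rose when adjusted over the list alone. Col3a1 (0.79, adjusted p = 0.075) and Dcn (0.56, adjusted p = 0.087) did not pass. Postn was not called with the control level as a block, where the mean shift of the list was 0.28 against 0.33, and within control levels the exact permutation p of the list was 0.125. The 1 call became 3 without Apoe-deficient replicate 5 or 6, 4 with array weights or the replicate number as a block and 2 with the white adipocyte score as a covariate. The exact permutation p was 0.0065 (adjusted 0.028) and the camera adjusted p with an estimated correlation 0.13. In the axon guidance list 1 of 31 genes fell, the netrin receptor gene Unc5c (-0.59, SE 0.13), and 2 fell when adjusted over the list alone. Unc5c lost its call without wild-type replicate 2 (-0.55, adjusted p = 0.11), among others. Dpysl5 (-0.58) and Dpysl3 (-0.32) did not pass. The exact permutation p was 0.0043 (adjusted 0.021) and the camera adjusted p with an estimated correlation 0.31. Within control levels the exact permutation p was 0.083, with a mean shift of -0.15 against -0.18.

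The remaining 7 lists that the preset test called did not pass the exact permutation test after adjustment. White adipocyte genes had a median of -0.66 with 0 of 14 members past the threshold (permutation adjusted p = 0.28, camera adjusted p = 0.58 with an estimated correlation). Brown adipocyte genes such as Cox8b (-1.66, adjusted p = 0.062) and Cidea (-1.23, adjusted p = 0.11) gave 0 of 7 (permutation adjusted p = 0.078, camera adjusted p = 0.31 with an estimated correlation). Ribosomal protein genes had a median of 0.045 with 0 of 43 past the threshold (permutation adjusted p = 0.25, camera adjusted p = 0.43 with an estimated correlation). In the interferon list Ifi47 (0.80) and Gbp2 (0.85) rose, 2 of 27 (permutation adjusted p = 0.25, camera adjusted p = 0.41 with an estimated correlation). In the unfolded protein list Pdia4 (1.08) rose, 1 of 31 (permutation adjusted p = 0.074, camera adjusted p = 0.31 with an estimated correlation). In the NF-kB list Cebpd (0.76) rose, 1 of 10 (permutation adjusted p = 0.068, camera adjusted p = 0.31 with an estimated correlation). Synaptic vesicle genes such as Vamp2 (-0.49, adjusted p = 0.055) gave 0 of 31 (permutation adjusted p = 0.17, camera adjusted p = 0.47 with an estimated correlation). Ifi47, Gbp2, Pdia4 and Cebpd each lost their call in at least 5 of the 11 fits without 1 array.

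The marker lists of noradrenergic neurons, general neurons and satellite glia showed no shift past the threshold. The axon guidance and synaptic vesicle lists, which hold neuronal genes, were called lower by the preset test, as given above. Of 24 noradrenergic neuron genes 0 passed over all genes, and the list's median was 0.02 (camera adjusted p = 0.32). Adjusted over the list alone, Slc18a1, a vesicular monoamine transporter gene, was higher (1.62, SE 0.43, adjusted p = 0.068 over all genes) and Gata2 lower (-0.46, adjusted p = 0.060 over all genes). General neuron genes had a median of -0.01 (camera adjusted p = 0.87) and satellite glia genes a median of 0.03 (camera adjusted p = 0.87), with Ttyh1 at -0.33 and Ednrb at -0.37. Of the 19 measured cholesterol synthesis genes 0 passed (median -0.02, camera adjusted p = 0.99), among them Msmo1 (0.38, adjusted p = 0.11) and Srebf2 (-0.32, adjusted p = 0.18). Other probe sets of Vamp2, Srebf2 and Ednrb went the opposite way (0.23, 0.09 and 0.02), and of the 2 others of Dpysl3 1 did (0.19) and 1 did not (-0.54). These tests do not show that the groups were alike. Myelinating Schwann cell genes varied between arrays, with a score of 1.01 in Apoe-deficient replicate 1 and at most 0.48 elsewhere. That array also had the highest actin 3' to 5' ratio, 5.16.

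**Figure D2:**
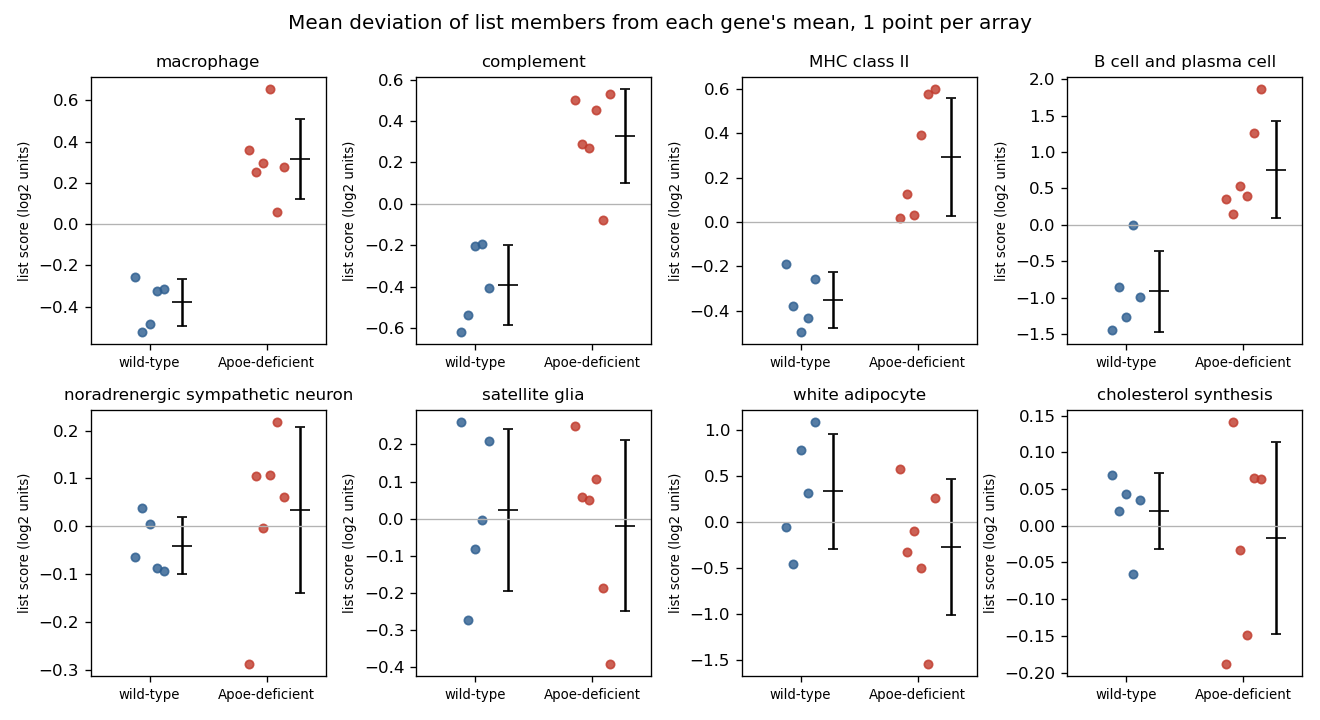
List scores, in log2 units, of 8 gene lists in wild-type (blue, n = 5) and Apoe-deficient (red, n = 6) ganglia, 1 point per array, with the mean and SD in black, a grey line at 0 and a separate vertical axis per list. The macrophage, complement, MHC class II and B and plasma cell scores were higher in the Apoe-deficient group (differences 0.70, 0.72, 0.64 and 1.67), and the other 4 lists overlapped between groups.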

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

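The tests in this part that regrouped the arrays were chosen before their results were seen. The tests of the 3 patterns on chromosome 7, macrophage genes and wild-type replicate 4 were chosen only after the result was seen.

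Regrouping gave different answers for genes and for lists. Of 100 splits of the 11 arrays, 1, the real one, called as many as 163 genes, and the highest other split called 2. Random regrouping of single arrays therefore did not give such a gene count in these splits. The splits treat arrays as separate units, so they cannot exclude an effect of arrays that share an animal. Nor can they exclude the hybridisation control level, whose 3 low arrays were all Apoe-deficient. With that level as a block 45 genes were called. For lists, 14 of the 100 splits called as many as the real 15, and the highest other split called 21, so chance could not be excluded for the number of called lists.

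The first pattern is the higher level of macrophage genes. A smaller share of neurons and glia would raise the genes of every other cell type alike. But the macrophage score rose beyond the mean of the endothelium and smooth muscle scores (difference 0.65, exact permutation p = 0.0043). The fibroblast and matrix score, left out of that contrast, also rose (0.33). A different make-up of the captured tissue was therefore not excluded. More captured fat would need a higher fat score, but that score differed by -0.61 between groups (exact permutation p = 0.18). With the white adipocyte score as a covariate 107% of the macrophage shift was kept. If fat brought in macrophage genes, this covariate could only raise the shift, because the fat score was lower in the Apoe-deficient group. The 107% therefore adds nothing against captured fat. With the hybridisation control level as a block 84.6% was kept (score difference 0.59, SE 0.12, against 0.70, SE 0.10), which argues against that level as the whole cause, although it may account for part; the median was 0.68 within the high level and 0.39 within the middle level, which held 1 Apoe-deficient array. Called members fell from 9 to 3 while the SE grew, the camera adjusted p was 7.94e-14 at the preset correlation and 0.117 at an estimated one, where it was 0.083 without the block, and the exact permutation p within levels, 0.042, was the smallest that 24 regroupings can give. An effect of the genotype remains a hypothesis, as do more macrophages or more transcript per macrophage, which bulk arrays cannot tell apart.

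The second pattern is a gathering of called genes around Apoe on chromosome 7. Of the 172 tested genes within 100 places of Apoe in gene order (GRCm38.p6), 8 were called, 5 lower and 3 higher, among them Slc1a5 (-1.40), Mrps12 (-0.82), Ercc2 (-0.69), Hnrnpl (0.94) and Med29 (0.89). Windows on other chromosomes overlapped and held 100 tested genes on each side, more than the window of Apoe, which only 72 tested genes precede. Of those windows 1.15% held as many called genes, with a median of 4 and a highest count of 9. Donor strain DNA linked to the targeted allele may account for part of these calls; Tyrobp, 1 of the 8, is also on the macrophage list, and which of the 2 applies was not tested. A sequence difference under single probe sets cannot be told apart from a changed transcript level. Only 1 other probe set could be examined, that of Aplp1, and it moved the same way (100%). Nudt19 (-1.35) is also on chromosome 7 but not among these 8 genes, and its other probe set gave -0.35. Whether donor strain DNA or a sequence difference accounts for the Nudt19 value was not tested.

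The third pattern is the array of wild-type replicate 4, whose Ighm signal was 14604 against a mean of 668 in the other wild-type arrays and 18200 in the Apoe-deficient arrays. Its Apoe signal of 13024 lay within the range of the other wild-type arrays, which argues against a wrong label. A mixture with Apoe-deficient RNA cannot be told apart from plasma cells in that sample: Ighm would need a share of 79.5% and Jchain one of 23%, and Apoe lay 17.0% below the mean of the other wild-type arrays. Over the 127 genes called higher without this array, antibody and B cell genes left out, its median share of the way to the Apoe-deficient mean was 22.9% (quartiles 8.82% and 48.6%), against -7.85% to 3.12% in the other wild-type arrays over as many genes chosen without each, but over the 131 genes called lower it was 64.7% (quartiles 45% and 83.6%), against -8.58% to 32.1%. Against a uniform mixture, the share over lower genes was above that of Apoe, and Calb2 (-2.41%), Ccl8 (-5.83%), Cd74 (-11.9%) and H2-Eb1 (-20.7%) lay below the mean of the other wild-type arrays, so the values point both ways, and plasma cells in the tissue of a single animal were not tested.

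Arrays that stood far from the rest of their group were sought in 200 groups of values, and 12 were found where chance gives about 10. On the log2(signal + 16) scale, Apoe-deficient replicate 3 had 4.64 for Apoe. Apoe-deficient replicate 4 had 11.5 for Igkv8-30, and Apoe-deficient replicate 6 had 4.50 for Slc35f4. Apoe-deficient replicate 5 had 5.43 for Cnmd and 7.37 for Ccl6. Wild-type replicate 1 had 8.81 for Postn, and wild-type replicate 4 had 9.15 for Igk and 8.43 for Birc3. Among list scores, Apoe-deficient replicate 1 had -0.27 for general neurons and 1.01 for myelinating Schwann cells. Apoe-deficient replicate 6 had -0.37 for the axon injury response, and wild-type replicate 4 had -0.063 for neurotrophic factor signalling.

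Probe sets outside the gene tests also held differences. Tested as probe sets with limma, 8 that name several genes and 8 with no gene named in the annotation used passed the threshold.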

How the results depend on the processing

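All but 4 of the 29 alternative settings were fixed before the data were examined. The 4 chosen after seeing the data were the hybridisation control level as a block, the omission of its 3 low arrays, and the white adipocyte score or the actin ratio as a covariate. The gene count of 163 lay within 1.5 times under other array scaling (151 with no step between arrays, 170 with median centring), pseudocounts, filters, probe set rules, variance models and both covariates. It was 668 with array weights (163 of them shared), 45 with the control level as a block and 24 without the 3 low arrays, where fewer arrays were tested. The cause of these moves was not tested. Leaving out 1 array gave 75 to 267 genes, below 163 without Apoe-deficient replicates 2, 3 and 4 (106, 75, 100) and wild-type replicates 1, 2, 3 and 5 (80, 77, 96, 77), and above it without Apoe-deficient replicates 1, 5 and 6 (260, 230, 239) and wild-type replicate 4 (267). The Apoe difference stayed past the threshold in each setting, from -7.08 to -6.17, and from -6.94 to -6.31 without 1 array. The 15 called lists became 0 with an estimated correlation, 10 with fry and 11 to 19 without 1 array; estimating the correlation widens the variance of a list mean, and the regrouped arrays called a median of 9 lists. Of 1655 alternative results of named genes 0 changed direction, and 11 of the 38 called genes besides Apoe passed in each setting that measured them. The white adipocyte list has no value with its own score as a covariate, being 0 by construction, and 13 named genes were not measured under the stricter filter. With the replicate number as a block over replicates 1 to 5, limma called 186 genes, 110 of them shared, and 12 lists, and Apoe differed by -6.75. The numbers gave no sign of pairing: deviations of same-numbered arrays correlated at 0.15, -0.18, -0.03, -0.0003 and -0.18, and in 0 of 5 cases did an array correlate best with its own number. Signal over background could not be set per probe set without detection calls, so low genes are the least certain.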

Other observations

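Some neuronal genes outside the noradrenergic list were lower in Apoe-deficient ganglia. The sodium channel subunit gene Scn3b differed by -0.85 (SE 0.11, limma adjusted p = 0.0011) and the potassium channel subunit gene Kcnab2 by -0.67 (adjusted p = 0.042), 2 of 24 ion channel genes. That list did not pass the preset test (camera adjusted p = 0.073) or the exact permutation test (adjusted p = 0.068), but it passed with fry (adjusted p = 0.022). Of 4 measured genes fixed as sensory neuron markers, too few to test as a list, Isl2 (-1.09) and Avil (-0.62, adjusted p = 0.022) fell. The remaining members, at -0.36 and -0.40, did not pass over all genes, but all 4 fell when adjusted over the list alone.

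In the lysosome list, the cathepsin genes Ctsh (1.18, SE 0.14) and Ctsc (1.24, SE 0.21) rose, 2 of 34 members, and the list did not pass (camera adjusted p = 0.17, exact permutation adjusted p = 0.057). Neurotrophic factor genes had a median of -0.25 (exact permutation adjusted p = 0.066, fry adjusted p = 0.039). Axon injury genes had a median of -0.16 (exact permutation adjusted p = 0.068, fry adjusted p = 0.059). The camera adjusted p was 0.071 for oxidative phosphorylation, 0.071 for immediate early genes, 0.16 for MHC class I, 0.16 for LXR targets, 0.18 for the circadian clock, 0.19 for endothelium, 0.34 for senescence, 0.48 for smooth muscle, 0.51 for the cell cycle, 0.60 for myelinating Schwann cells and 0.97 for oxidative stress. Too few genes were measured to test the adrenal (4), enteric or cholinergic (2), erythrocyte (1), exocrine pancreas (4) and skeletal muscle (4) lists.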
